A study of Mus musculus with 32 samples.

How the data were processed

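RNA was measured by sequencing in livers of 32 mice on a high-fat diet, in 4 groups of 8: males and females labelled *Ubiad1*+/+ (WT) or *Ubiad1*+/- (Het). Per the labels' protocols, RNA was extracted with a NucleoSpin kit and strand-specific TruSeq mRNA libraries were made. Each label names a separate mouse, and the mouse was the unit of replication. The replicate numbers only name the mice and pair none of them across groups.

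The authors deposited 2 tables, 1 per sex, each with counts per gene and mouse and the columns of their own comparison. The deposited counts were whole numbers that summed to a different total in each mouse, and they were taken as raw read counts per gene. Per the submitters' processing notes, reads were aligned with HISAT2 2.1.1 and counted with featureCounts 2.0.1. The genome build, the annotation, the strand setting of the counting and the gene filter were not given in the sources used here, so no coordinates are printed. Reads shared between near-identical genes, or between overlapping or antisense genes, therefore could not be assigned with certainty. The lowest total count of a listed gene over 16 mice was 244 in the male table and 296 in the female table, so rarely transcribed genes were not analysed here. The deposited log2 fold changes and the deposited p-value and adjusted p-value columns belong to the authors' comparison. Per the file headers the tables hold dispersion estimates of a negative binomial model, and the authors' test and adjustment are not given in the sources used here. The authors' p-values and log2 fold changes were used only for a check beside the refit. The 32 columns of normalised values per mouse were not used.

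Total counts per mouse over the listed genes ranged from 5894091 to 32943436. Levels in CPM are counts relative to the scaled library total, and a gene at 1 CPM thus rested on about 6 counts in the shallowest library, and *Ubiad1* on 42 to 232 counts per mouse. In every pair of mice of a group the counts differed by far more than sampling noise (lowest chi-square per degree of freedom 21.6 in males and 18.5 in females), so no library was counted as a duplicate.

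Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Within each sex, Het was compared with WT by edgeR's quasi-likelihood test after TMM scaling, with filterByExpr, which removed 0 of 11708 genes in males and 0 of 12253 in females. Adjusted p is Benjamini-Hochberg over all genes of the table, and a gene counted as called at an adjusted p under 0.05. Standard errors (SE) of log2 fold changes are those implied by the quasi-F statistic. Levels are TMM-scaled CPM, given as mean ± SD over 8 mice. The difference between the sexes was the interaction of genotype and sex in 1 edgeR fit over all 32 mice and the 11440 genes listed in both tables. Sex and library batch could not be told apart, because each sex was deposited as its own table and the share of counts in mitochondrial genes differed between them, so levels were compared within a sex only.

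A total of 32 gene lists were fixed before the data were examined, as were the tests, the alternatives listed beforehand and the rule for named genes. Lists with at least 5 measured members (25 in males and 27 in females) were tested with limma's camera on log2 CPM (prior count 2), with an inter-gene correlation preset at 0.01 and also estimated, and Benjamini-Hochberg over the lists of a sex. The rotation test fry of limma, which tests each list by itself, was also fixed beforehand and adjusted in the same way. Members were also adjusted over the list alone. The mean log2 CPM of each list per mouse was compared by an exact two-sided permutation test over all 12870 assignments of the labels. The differences of these list means between the sexes were tested with 100000 permutations of the genotype labels within sex.

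The rule named *Ubiad1*, the 8 highest and 8 lowest fold changes per sex among called genes with a mean normalised count of at least 20, without predicted gene models, the 4 members of each list with the smallest p, and the 5 genes with the smallest p for the sex difference. Where fewer than 8 genes passed, the rule filled up by smallest p, and such genes are said not to pass. It also named up to 10 genes called in the same direction in both sexes, of which there were 0, and genes that check the substrain and sex labels.

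Transcript length and GC content came from GENCODE gene models of the mouse, matched by Ensembl identifier for 98.9% of genes in the male table and 98.6% in the female table. They may belong to another annotation release than the authors used. For each library, the rank correlation across genes of its deviation from the mean of the 16 libraries with transcript length and with GC content was computed. A fit with these trends removed used natural splines with 4 degrees of freedom for each of length and GC, as offsets in edgeR. A clock score per mouse was the mean of 6 evening genes minus that of 3 morning genes of the circadian clock.

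Alternatives comprised other thresholds and filters, Benjamini-Yekutieli adjustment, DESeq2 1.42.0 with its size factors, 1 fit over all 4 groups, each mouse left out in turn, other settings of the list tests, and the authors' deposited adjusted p. Fits with the trends removed, without the 5 male libraries that rose most with length or the 4 female libraries that fell most with GC content (cutoffs 0.25 and -0.5, libraries with the opposite trend kept), and with the clock score as a covariate were also run. The edgeR tests per sex, with and without trend removal, the sex difference and the camera test were tested on simulated counts before use. At each of 2 folds, 100 genes were changed for the tests per sex and 195 for the sex difference. For the camera test 1 list was raised in each sex, and it was recovered in both. In males, over 11707 genes, edgeR recovered 62% of genes changed 1.5-fold and 88% of those changed 2-fold, with 5.66% false among the calls. In females, over 12253 genes, it recovered 40% and 83%, with 3.15% false. For the sex difference, over 11440 genes, it recovered 26.7% and 68.7%, with 6.06% false. The simulated counts were drawn gene by gene, with no correlation between genes and no length or GC trend of a library. These rates, and the recovered lists, therefore do not give the error rates for the real counts. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.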

Results

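Liver RNA was sequenced from 32 mice of the C57BL/6N strain fed a high-fat diet. *Ubiad1* encodes a prenyltransferase that makes a form of vitamin K and binds HMG-CoA reductase, the rate-limiting enzyme of cholesterol synthesis. The study asked how the loss of a copy of this gene affects the liver in each sex. There were 8 males and 8 females labelled *Ubiad1*+/+, called WT here, and 8 males and 8 females labelled *Ubiad1*+/-, called Het. Total counts per mouse were 5894091 to 32943436 in WT males, 10585249 to 21910106 in Het males, 16435474 to 30400071 in WT females and 15942387 to 28523139 in Het females. The sex labels were checked first. *Xist*, the transcript of the inactive X chromosome, was listed in the female table alone, and the Y-linked genes of the check were listed in the male table alone.

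*Ubiad1* (ENSMUSG00000047719) was not lower in the mice labelled heterozygous. In males it stood at 6.96 ± 0.459 CPM in WT and 7.51 ± 1.09 CPM in Het (SD, n = 8 per group). The log2 fold change was 0.11 ± 0.09 (SE, edgeR adjusted p = 0.489), and 5 of 8 Het mice lay above the WT median. In females it stood at 5.97 ± 0.600 CPM in WT and 6.86 ± 0.704 CPM in Het (log2 fold change 0.20 ± 0.09, adjusted p = 0.338), with 6 of 8 Het mice above the WT median. The 95% interval of the fold was 0.944 to 1.23 in males and 1.0025 to 1.32 in females, so a fall to 0.5 of the WT level lay outside both intervals. The transcript level therefore did not separate the genotypes, and Het and WT denote the mice labelled heterozygous and labelled wild type in every comparison. The 15 measured neighbours of *Ubiad1* on its chromosome had a median log2 fold change of 0.05 in males (limma camera adjusted p = 0.806) and 0.08 in females (adjusted p = 0.0953), and 0 of them were called in either sex.

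**Figure D1:**
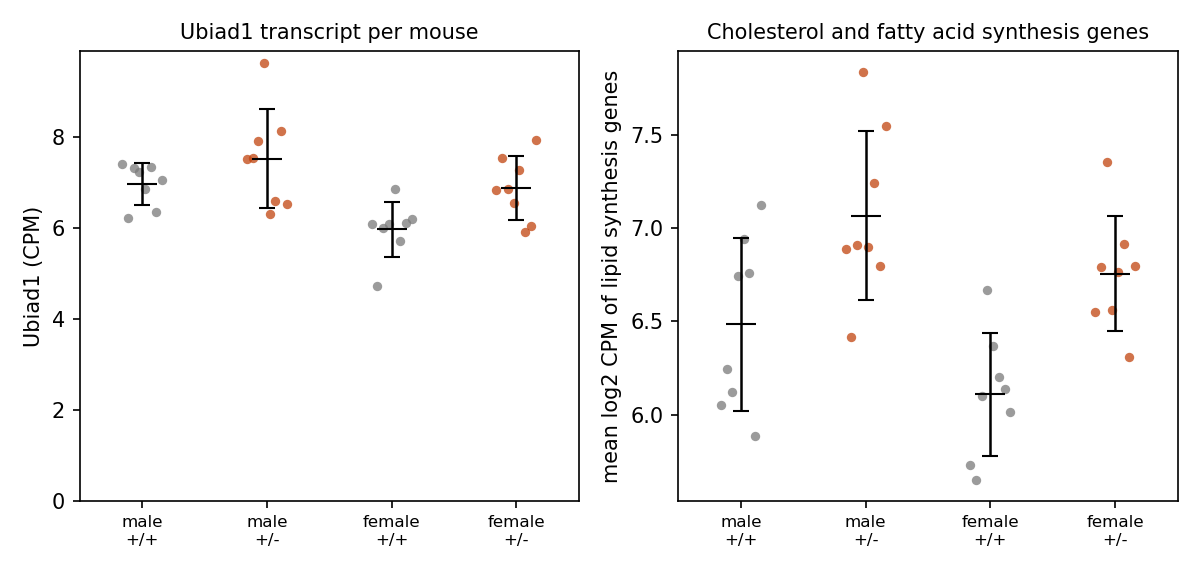
*Ubiad1* in CPM (left) and the mean log2 CPM of the cholesterol, fatty acid and triglyceride synthesis genes (right), 1 point per mouse in the 4 groups by label, with bars for mean ± SD (n = 8). *Ubiad1* was 6.96 in WT males and 7.51 in Het males, and the lipid synthesis mean was 6.11 in WT females and 6.75 in Het females.

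In females labelled heterozygous, genes of fatty acid, triglyceride and cholesterol synthesis were higher than in females labelled wild type. *Thrsp*, which promotes fatty acid synthesis, rose from 50.8 ± 25.6 to 197 ± 129 CPM (SD, n = 8 per group), a log2 fold change of 1.95 ± 0.39 (SE, edgeR adjusted p = 0.0451). *Hmgcr*, which encodes HMG-CoA reductase, rose from 51.6 ± 13.3 to 123 ± 48.6 CPM (log2 fold change 1.26 ± 0.22, adjusted p = 0.0196). *Lpin1*, a phosphatidate phosphatase of triglyceride synthesis, rose by 1.59 ± 0.25 on the log2 scale (adjusted p = 0.0140), and all 3 genes were above the WT median in 8 of 8 Het mice. *Hes1*, a transcriptional repressor downstream of Notch, fell from 11.7 ± 1.77 to 4.90 ± 0.965 CPM (log2 fold change -1.25 ± 0.13, adjusted p = 0.000126). Every one of the 8 Het mice was below the lowest WT mouse for *Hes1* (highest Het 6.49, lowest WT 9.28 CPM).

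Of the 24 measured genes of fatty acid and triglyceride synthesis, 21 had positive log2 fold changes, with a median of 0.69. Over all genes, 5 of them rose (*Thrsp*, *Lpin1*, *Lpin2*, *Acly* and *Acaca*), and 12 rose when adjusted over the list alone. *Acly*, which makes cytosolic acetyl-CoA, had a log2 fold change of 1.10 ± 0.19 (adjusted p = 0.0212), and *Acaca*, which makes malonyl-CoA, had 0.84 ± 0.17 (adjusted p = 0.0451), each with 8 of 8 Het mice above the WT median. All 20 cholesterol synthesis enzymes had positive log2 fold changes, with a median of 0.49. Over all genes 1 of them rose, *Hmgcr*, and 12 rose when adjusted over the list alone, among them *Lss*, *Dhcr7* and *Hsd17b7*. The camera test with a preset correlation called both lists (adjusted p = 3.5e-12 for each). With an estimated correlation the adjusted p was 0.158 for fatty acid and triglyceride synthesis and 0.162 for cholesterol synthesis. Taken per mouse, the mean log2 CPM of the first list was 0.69 ± 0.17 higher in Het (SE, n = 8 per group, exact permutation test, p = 0.0014, adjusted p = 0.0378 over 27 lists). That of the second was 0.60 ± 0.16 higher (exact permutation test, p = 0.00342, adjusted p = 0.0378). In both lists 8 of 8 Het mice lay above the WT median.

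**Figure D2:**
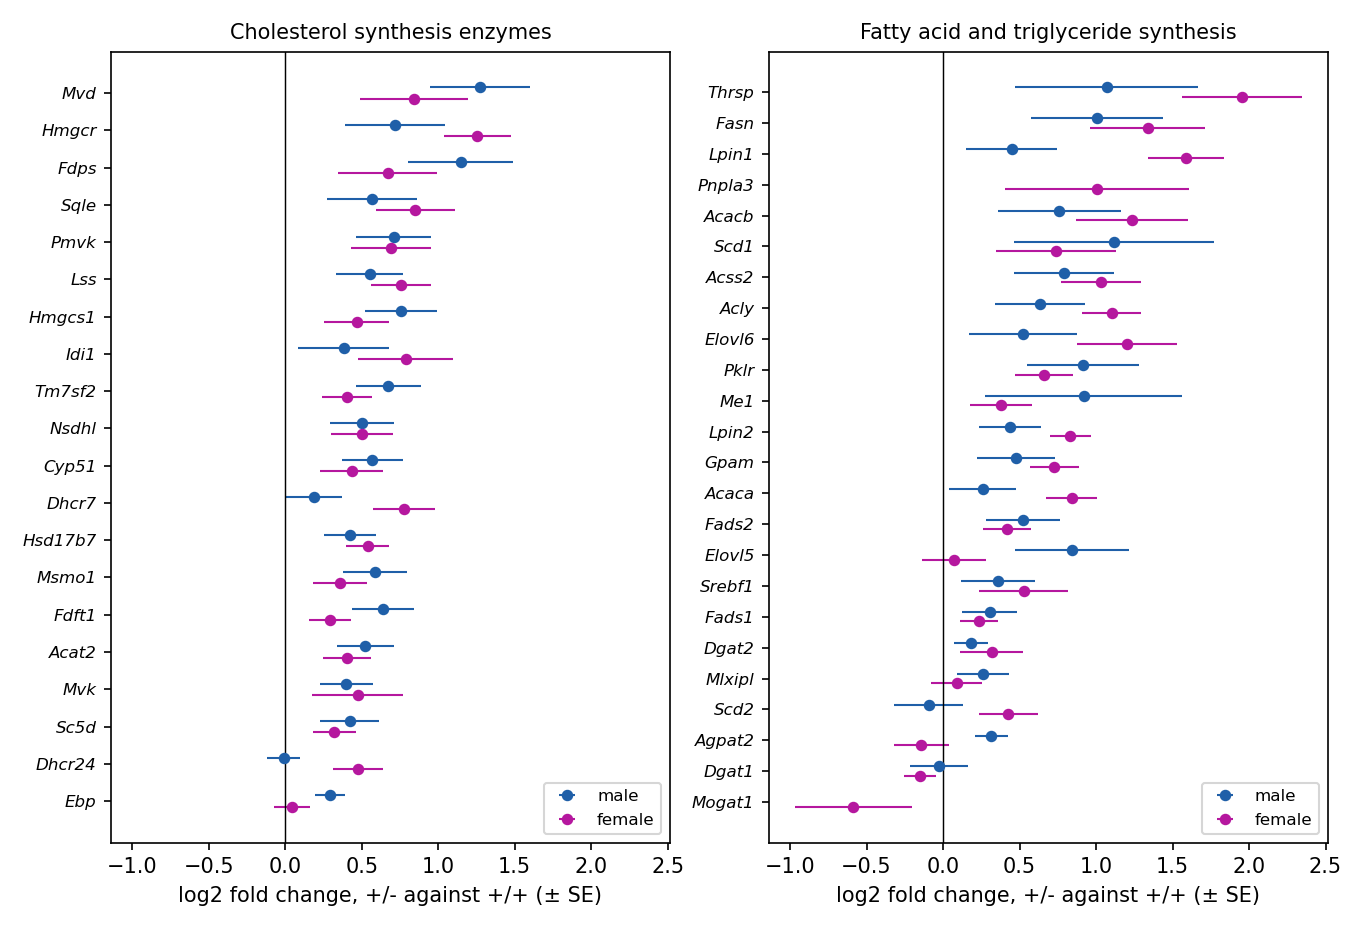
Log2 fold change, Het over WT by label, of each measured gene of cholesterol synthesis (left) and of fatty acid and triglyceride synthesis (right), in males and females, with bars for SE (n = 8 per group). All 20 cholesterol synthesis genes were positive in females and 19 of 20 were positive in males.

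The list of glucose metabolism and insulin signalling was also higher in Het females (16 of 19 positive, median log2 fold change 0.21, camera adjusted p = 0.00189, adjusted p = 0.158 with an estimated correlation). Its mean per mouse was 0.35 ± 0.09 higher (exact permutation test, p = 0.0042, adjusted p = 0.0378), with 8 of 8 Het mice above the WT median. *Pck1*, the rate-limiting enzyme of gluconeogenesis, was the gene of this list called over all genes and rose from 1004 ± 249.8 to 2056 ± 706 CPM (log2 fold change 1.03 ± 0.20, adjusted p = 0.0451). Adjusted over the list alone 2 genes rose, *Pck1* and *Igfbp1*, an insulin-repressed binding protein. Sterol regulation, uptake and export had 18 of 20 positive genes (median 0.20, camera adjusted p = 0.000395, adjusted p = 0.162 with an estimated correlation). Over all genes 0 of its members were called, and 2 rose when adjusted over the list alone, *Pcsk9* and *Abcg1*. Its mean per mouse was 0.24 ± 0.08 higher (exact permutation test, p = 0.0123, adjusted p = 0.0829), with 7 of 8 Het mice above the WT median. With length and GC trends removed this difference was 0.15 ± 0.03 and passed (exact permutation test, adjusted p = 0.00839; camera with an estimated correlation, adjusted p = 0.0371).

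Markers of other liver cells were higher in Het females with the preset correlation: 8 of 8 endothelial genes (median 0.23, adjusted p = 0.00794), 12 of 15 macrophage genes (0.21, adjusted p = 0.0204) and 10 of 12 stellate cell genes (0.25, adjusted p = 0.0353). None of these 3 calls held with an estimated correlation (adjusted p = 0.545 for each), and 0 of their genes were called or passed when adjusted over the list alone. Without WT 2, WT 6, WT 8 and Het 6, the 4 libraries whose deviations fell most with GC content, all 3 calls ended (adjusted p = 0.308, 0.266 and 0.930), whereas with each library's length and GC trend removed all 3 lists stayed called (adjusted p = 0.0199, 0.000219 and 0.0359). The endothelial call ended without Het 6 (0.0675), and the macrophage call without WT 4 (0.0563), Het 1 (0.0908) or Het 6 (0.0830). The stellate call ended without WT 2 (0.188), WT 4 (0.0563), Het 6 (0.179) or Het 7 (0.0709). Immediate early genes had 5 of 7 positive members (median 0.30, adjusted p = 0.0339, adjusted p = 0.442 with an estimated correlation), and *Btg2* alone rose when adjusted over the list alone. That call ended without WT 3 (0.0709), WT 7 (0.0629), Het 1 (0.0819), Het 7 (0.0514) or Het 8 (0.0559), with length and GC trends removed (0.194) and with the clock score as a covariate (0.0613). Genes encoded in the mitochondrial genome were lower in 12 of 13 cases (median -0.28, adjusted p = 0.00189, adjusted p = 0.545 with an estimated correlation). The mitochondrial share of counts was 8.40% to 9.98% in WT 2, WT 6, WT 8 and Het 6, whose deviations fell with GC content (rank correlation across genes -0.75 to -0.64), and 5.77% to 8.14% in the other 12 females. With each library's length and GC trend removed, the median of the mitochondrial genes was 0.01 and the list was not called (adjusted p = 0.814), nor was it without these 4 libraries (adjusted p = 0.619).

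Among the other genes with the largest called changes in Het females were *Tsc22d3*, a glucocorticoid-induced gene (log2 fold change 1.43 ± 0.21, adjusted p = 0.0120), and *Noct*, a rhythmic phosphatase of NADP cofactors (1.53 ± 0.26, adjusted p = 0.0196), both above the WT median in 8 of 8 Het mice. *Arl4d* (1.67), *Ccn2* (1.66) and *Plk3* (1.25) also rose, and *Rasl11b* (-0.79), *Smim36* (-0.63), *Fgl1* (-0.60), *Trim68* (-0.58) and *Fahd1* (-0.52) fell. With the trends removed *Plk3* (adjusted p = 0.161), *Fgl1* (0.173) and *Smim36* (0.0504, against 0.0451 before) did not pass. A call lost in this way does not by itself show that the fold shrank. *Zfp472* (-0.59, adjusted p = 0.0559) and *Lpar6* (-0.45, adjusted p = 0.0604) did not pass. Of the 27 lists tested, the other 18 were not called (adjusted p from 0.0828 to 0.920). Among them, fatty acid oxidation had 17 of 29 negative genes (median -0.12, adjusted p = 0.0828), and *Cyp4a10*, *Cyp4a14* and *Decr1* fell when adjusted over the list alone. Genes of the vitamin K cycle (median 0.05, adjusted p = 0.780) and of coenzyme Q synthesis (median -0.01, adjusted p = 0.862) were not called.

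In all, edgeR called 35 genes in females, 28 higher and 7 lower in Het. DESeq2 called 239 (141 higher, 98 lower), 1 fit over all 4 groups called 76 (50 higher, 26 lower), and the fit with length and GC trends removed called 88 (52 higher, 36 lower), of which 23 were among the 35. Without the 4 libraries whose deviations fell most with GC content 2 genes were called, and with 1 mouse left out the count ran from 3 (without WT 8) to 69 (without Het 6), with *Hes1* and *Tsc22d3* called in each of the 16 fits. *Hmgcr* and *Lpin1* were called in 15 of these fits, *Acly* in 13, *Acaca* in 4, and *Thrsp* and *Pck1* in 3 each. *Arl4d* and *Smim36* were called in 4, *Plk3* and *Fgl1* in 3, *Ccn2* and *Trim68* in 2 and *Rasl11b* in 1.

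**Figure D3:**
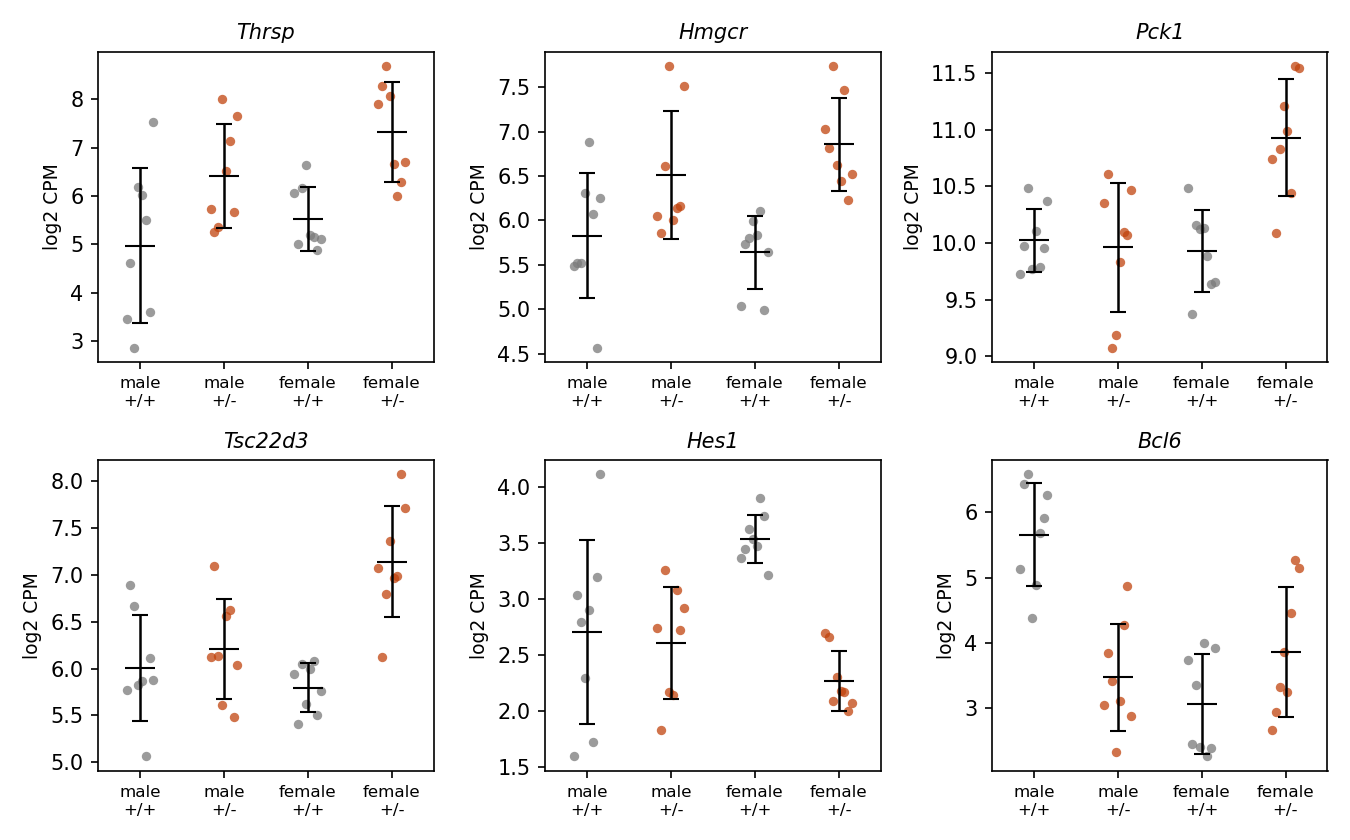
Log2 CPM of 6 genes, 1 point per mouse in the 4 groups by label, with bars for mean ± SD (n = 8). *Hes1* in females did not overlap between the labels, and *Bcl6* in males fell from a mean of 57.0 to 12.9 CPM.

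In males labelled heterozygous, *Bcl6*, a transcriptional repressor of lipid metabolism genes, fell from 57.0 ± 27.6 to 12.9 ± 8.02 CPM (SD, n = 8 per group), a log2 fold change of -2.13 ± 0.37 (SE, edgeR adjusted p = 0.0101), below the WT median in 8 of 8 Het mice. *Mvd*, an enzyme of the mevalonate pathway, rose from 15.4 ± 6.94 to 37.0 ± 17.9 CPM (log2 fold change 1.27 ± 0.33, adjusted p = 0.0470), above the WT median in 8 of 8. *Gck*, the glucokinase of the liver, rose by 0.57 ± 0.13 on the log2 scale (adjusted p = 0.0350). *Foxo1*, a transcription factor of gluconeogenic genes, had a log2 fold change of -0.45 ± 0.12 (adjusted p = 0.0461). With length and GC trends removed *Bcl6* stayed called, while *Mvd*, *Gck* and *Foxo1* did not. Across all called genes, those that rose had short transcripts (median 1322 nt) and those that fell had long ones (median 6177 nt), against 3085 nt over all genes. The rank correlation of log2 fold change with transcript length was -0.49 across genes, which are not independent replicates.

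Of the 20 cholesterol synthesis enzymes, 19 had positive log2 fold changes in males (median 0.56). Over all genes 1 of them rose, *Mvd*, and 14 rose when adjusted over the list alone, among them *Hmgcs1*, *Fdps* and *Tm7sf2*. Of 22 genes of fatty acid and triglyceride synthesis, 20 were positive (median 0.50), and 0 were called, over all genes or adjusted over the list alone. The camera test called both lists with the preset correlation (adjusted p = 1.5e-07 and 0.000219), and with an estimated correlation the adjusted p was 0.769 and 0.777. Per mouse, the mean of cholesterol synthesis was 0.60 ± 0.21 higher in Het (exact permutation test, p = 0.0120, adjusted p = 0.0903 over 25 lists), with 8 of 8 Het mice above the WT median. That of fatty acid and triglyceride synthesis was 0.56 ± 0.29 higher (exact permutation test, p = 0.0699, adjusted p = 0.223), with 7 of 8 above. Neither passed the correction over lists. Fits without WT 1 to WT 5, the 5 WT libraries whose deviations rose with transcript length, kept only WT 6, WT 7 and WT 8 as WT. Deviations of WT 7 and WT 8 fell with length (rank correlation -0.27 and -0.29). A lost call or changed sign in these fits therefore cannot be put down to the trend alone. There the cholesterol list stayed called (camera adjusted p = 4.4e-09) and the fatty acid and triglyceride list was not called (adjusted p = 0.117). With the clock score as a covariate the latter was not called either (adjusted p = 0.103). Both stayed called with length and GC trends removed (adjusted p = 5.5e-10 and 5.3e-06).

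Nuclear-encoded genes of oxidative phosphorylation were positive in 25 of 26 cases in males (median 0.23, camera adjusted p = 1.6e-07, adjusted p = 0.769 with an estimated correlation). *Ndufs3* (log2 fold change 0.65 ± 0.12, adjusted p = 0.0132) and *Ndufb10* (0.45 ± 0.11, adjusted p = 0.0361), subunits of respiratory complex I, rose in 8 of 8 Het mice against the WT median. These 2 and *Sdhb* rose when adjusted over the list alone. With length and GC trends removed the list was still called with the preset correlation, but its median was 0.09, its mean per mouse went from 0.28 ± 0.10 to 0.15 ± 0.06, and *Ndufs3* (0.48, adjusted p = 0.0529) and *Ndufb10* (0.23, adjusted p = 0.193) did not pass. Without WT 1 to WT 5 the list was not called (adjusted p = 0.913). Coenzyme Q and isoprenoid genes were positive in 14 of 16 cases (median 0.17, adjusted p = 0.00789, adjusted p = 0.769 with an estimated correlation). Over all genes 0 of them were called, and *Coq2*, *Coq6*, *Coq7* and *Coq8b* rose when adjusted over the list alone. Their mean per mouse was 0.16 ± 0.04 higher, with 8 of 8 Het mice above the WT median (exact permutation test, p = 0.00497, adjusted p = 0.0903). With the trends removed the difference shrank to 0.08 ± 0.03 (median 0.09) and the list was not called (camera adjusted p = 0.0953), nor was it without WT 1 to WT 5 (adjusted p = 0.666). Fatty acid oxidation had 28 of 29 positive genes (median 0.23, adjusted p = 8.6e-05, adjusted p = 0.777 with an estimated correlation), with 0 called over all genes or when adjusted over the list alone. Without WT 1 to WT 5 this list turned to the opposite sign (adjusted p = 0.877), and with the clock score it was not called (adjusted p = 0.353), while with the trends removed it stayed called (adjusted p = 0.000109). Xenobiotic metabolism had 11 of 12 positive genes (median 0.29, adjusted p = 0.0250, adjusted p = 0.777 with an estimated correlation), and *Nr1i2* and *Cyp26a1* rose when adjusted over the list alone. That call ended without WT 1 (0.0641), WT 3 (0.0686) or Het 5 (0.0568), without WT 1 to WT 5 (0.913) and with the clock score (0.634), but not with the trends removed (0.0398).

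Endothelial markers were lower in all 8 measured cases in Het males (median -0.39, camera adjusted p = 0.0034, adjusted p = 0.769 with an estimated correlation). Over all genes 0 of them were called, and *Cdh5*, *Kdr*, *Stab2* and *Tek* fell when adjusted over the list alone. Without WT 1 to WT 5 the list was not called (adjusted p = 0.365) and *Cdh5* was 0.06 higher on the log2 scale, whereas with length and GC trends removed the list stayed called (adjusted p = 0.00309) and its mean per mouse was 0.35 ± 0.18 lower, against 0.41 ± 0.18 before. The called genes *Adgrl4*, a receptor of endothelial cells (log2 fold change -0.86 ± 0.18, adjusted p = 0.0224), and *Rgs5*, a pericyte gene of the stellate list (-0.62 ± 0.13, adjusted p = 0.0240), fell in 8 of 8 Het mice against the WT median. With length and GC trends removed neither gene was called. The stellate list was not called (median -0.21, adjusted p = 0.0746). Acute phase and inflammatory genes were lower in 14 of 15 cases (median -0.77, mean -1.63, adjusted p = 0.0280, adjusted p = 0.852 with an estimated correlation). None was called over all genes, and 6 fell and 1 rose when adjusted over the list alone. *Saa1*, a serum amyloid gene that shares reads with near-identical copies, stood at 16229 CPM in WT 1 and 17801 CPM in WT 3, and at 74.1 to 1141 CPM in the other 14 males. The acute phase call ended without WT 1 (0.165), WT 3 (0.147), Het 6 (0.0879), Het 7 (0.0833) or Het 8 (0.0878), and without WT 1 to WT 5 together (0.760), and the list turned to the opposite sign with the clock score as a covariate (adjusted p = 0.769). It stayed called with length and GC trends removed (adjusted p = 0.00309), with a mean per mouse 0.89 ± 0.59 lower, against 0.77 ± 0.58 before.

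Among the other genes with the largest called changes in Het males, *Scand1* (2.01), *Bloc1s1* (1.30), *Ndufaf8* (1.18) and *Rex1bd* (1.07) rose, each above the WT median in 8 of 8 Het mice. *Mir6236* (1.59), *Mup-ps22* (1.48) and *Rps4l* (1.06) also rose, and their counts are uncertain because they share sequence with near-identical copies. *Armcx4* (-1.11), *Arhgap31* (-0.92), *F8* (-0.83), *Adamts9* (-0.82), *Gfod1* (-0.80) and *Ptch1* (-0.79) fell. *Pcna*, the sliding clamp of DNA replication, rose by 0.26 ± 0.07 (adjusted p = 0.0489), while the cell cycle list was not called (adjusted p = 0.831). With length and GC trends removed, *Bloc1s1* and *Rex1bd* stayed called and the other called genes named in this paragraph did not. Levels of *Scand1* were low, at 0.203 to 1.17 CPM in WT. Of the 25 lists tested, 17 were not called by camera (adjusted p from 0.0746 to 0.913). Among them were the vitamin K cycle (median -0.04, adjusted p = 0.889), the sterol regulation genes (median 0.13, adjusted p = 0.143) and glucose metabolism (median 0.01, adjusted p = 0.831). The sterol regulation genes passed by fry (adjusted p = 0.0446), a test not run with the trends removed.

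In all, edgeR called 297 genes in males, 193 higher and 104 lower in Het. DESeq2 called 901 (452 higher, 449 lower) and 1 fit over all 4 groups called 329 (122 higher, 207 lower), of which 163 were among the 297. With each library's length and GC trend removed 7 genes were called (*Rex1bd*, *Bcl6*, *Bloc1s1*, *Eif3f*, *Rbm8a*, *Stx4a* and a predicted gene), and without WT 1 to WT 5 edgeR called 0, with 901 at an unadjusted p under 0.05. With 1 mouse left out the count ran from 70 (without WT 2) to 1342 (without WT 8). *Bcl6*, *Rex1bd*, *Bloc1s1*, *Ndufs3* and *Scand1* were called in each of the 16 fits, *Adgrl4* in 15, *Ndufaf8* in 14 and *Rgs5* in 13. *Gck* was called in 7 of these fits, *Foxo1* in 4, *Mvd* in 3, and *Pcna*, *Ptch1* and *Adamts9* in 2 each.

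**Figure D4:**
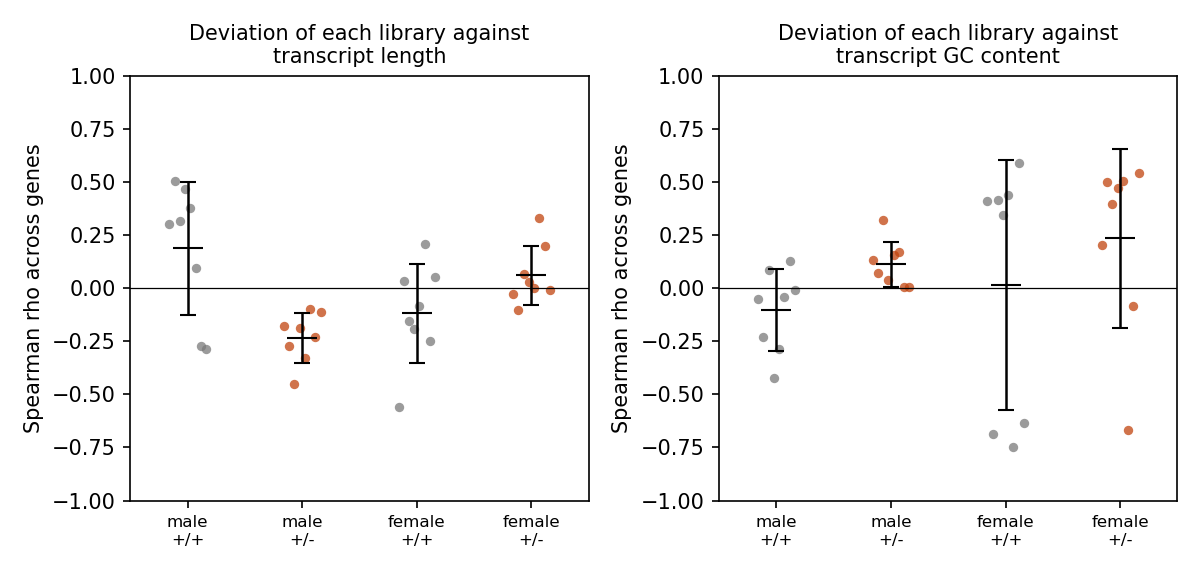
Spearman rho across genes between each library's deviation from the mean of its sex and transcript length (left) or GC content (right), 1 point per mouse in the 4 groups by label, with bars for mean ± SD (n = 8). Rho with length was 0.303 to 0.503 in WT 1 to WT 5 of the males and -0.453 to -0.0984 in the Het males.

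The comparison of both sexes asked whether the difference between the labels was alike in males and females. *Akap13*, a scaffold of protein kinase A, had a log2 fold change of -0.32 in males and 0.57 in females (difference -0.89, edgeR interaction, n = 8 per group). *Hipk2*, a kinase of the stress response, had a male minus female difference of -1.22, while *Eif3f* (0.98), *Fahd1* (1.03) and *Ndufs3* (0.86) differed the other way. Of the 11440 genes listed in both tables, 548 had a difference past the threshold, 244 greater in males and 304 greater in females. *Pck1* (-1.03, adjusted p = 0.0394), *Tsc22d3* (-1.24) and *Bcl6* (-3.06, adjusted p = 0.00626) were among them. With length and GC trends removed *Pck1* did not pass (-1.02, adjusted p = 0.0638), while *Tsc22d3* (adjusted p = 0.0422) and *Bcl6* (adjusted p = 0.0131) did. *Hmgcr* (-0.54, adjusted p = 0.458), *Thrsp* (-0.89, adjusted p = 0.512) and *Mvd* (0.44, adjusted p = 0.652) were not, so their effects were not shown to differ between the sexes.

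Per mouse, the cholesterol synthesis difference was 0.60 in males and 0.60 in females (male minus female 0.01, permutation test, adjusted p = 0.981 over 25 lists). For fatty acid and triglyceride synthesis the difference between the sexes was -0.12 (adjusted p = 0.809). The endothelial markers had the smallest p, with -0.64 (p = 0.00488, adjusted p = 0.105), and 0 of the 25 lists passed, with 4 at an unadjusted permutation p under 0.05. No gene was called in both sexes by edgeR, against 0.441 expected for higher and 0.0545 for lower genes. With so few expected, an overlap of 0 does not decide whether the sexes share effects. At an unadjusted p under 0.05 in both, 434 genes were shared, of which 67 were higher in both, 28 lower in both and 339 opposite (199 opposite expected). DESeq2 called 23 genes in both sexes, against 18.3 expected, 6 of them higher in both and 17 opposite. Across the 11440 genes, which are not independent replicates, the log2 fold changes of the sexes had a Pearson r of 0.02 and a Spearman rho of -0.10. Over all genes of each sex, log2 fold changes had a rank correlation with transcript length of -0.49 in males and 0.28 in females. With GC content it was 0.24 and 0.36. These opposite length trends may therefore enter the opposite genes and the sex differences. With length and GC trends removed, 162 genes were opposite at an unadjusted p under 0.05, against 130 expected, and Spearman rho was -0.04. With the trends removed the count of sex differences was 118 (63 greater in males, 55 in females), and with the statistics rescaled to their robust spread it was 0 in the edgeR fit, with 466 at an unadjusted p under 0.05.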

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

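The tests of the *Ubiad1* level, the fits with length and GC trends removed, the thinning, the pooled lipid mean and the clock score were chosen only after the results they weigh had been seen, while the draws of labels, the gap between mice and the interaction test were set beforehand.

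*Ubiad1* was not lower in the mice labelled heterozygous, in either sex. A loss of 0.5 of the transcript hidden by the spread between mice is argued against, since the lower end of the 95% interval of the fold was 0.944 in males and 1.0025 in females. Labels exchanged between mice stay open, since 0 of 32 mice lay below 0.75 times the WT median of their sex, so the transcript separated no mice and this test decides nothing. It also stays open, as untested here, that transcripts of the altered allele may be counted over exons that remain, or that the other allele may make up for the loss. Counts per gene, with no counts per exon, leave these open.

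In males, genes that rose were short and genes that fell were long. With each library's length and GC trend removed, 2.36% of the 297 called genes were still called in the same direction, so a trend of single libraries is a candidate explanation for most of these calls. The median size of the called log2 fold changes went from 0.45 to 0.28 while their median SE went from 0.10 to 0.09, so in the median the folds shrank and the SE did not grow. These medians do not say why each single call ended. Genes at an unadjusted p under 0.05 in edgeR went from 2754 to 1765. With all libraries thinned to 5894091 counts, the rank correlation with length stayed at a median of -0.43 (-0.43 to -0.42 over 10 thinnings). This argues against the unequal number of counts itself as the source of the length pattern. Thinning keeps the expected share of each gene in a library. It therefore cannot weigh a length trend that arose together with depth when the libraries were made. Thinning also cut the called genes to 16 to 58, against 297. Whether the loss of counts or the equal depth did so was not tested. An effect of genotype on long and short transcripts cannot be excluded, because the library trends went partly with the label. Deviations of 5 WT libraries and 0 Het libraries rose with length (rank correlation above 0.25). Those of 2 WT and 3 Het libraries fell with it (below -0.25). *Bcl6* kept a log2 fold change of -2.08 (edgeR adjusted p = 0.0417) with the trends removed, but a single gene does not bear on that question.

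The mean of the 2 lipid synthesis lists, pooled after both had been seen to be higher, differed by 0.65 ± 0.16 on the log2 scale in females and 0.58 ± 0.23 in males (SE), though in males neither list passed the permutation test (adjusted p = 0.0903 and 0.223), and with an estimated correlation neither passed in males (0.769 and 0.777) or females (0.162 and 0.158). Length and GC trends are argued against in both, since the difference was 0.594 in females and 0.580 in males with the trends removed, although the fatty acid and triglyceride list in males was not called without WT 1 to WT 5 (adjusted p = 0.117). In females the lipid difference was 0.674 with a clock score as covariate, so the score did not account for 0.5 of it. The score differed by 0.839 between the labels there (exact permutation test, p = 0.366), so the covariate could remove little. Clock phase beyond this score therefore stays open in females. In males the lipid difference was 0.403 ± 0.237 with the covariate. That is within 1 SE of 0.291, the level at which the clock would account for 0.5 of it. The clock score and genotype therefore cannot be told apart there. The score was lowest in WT 1 (-4.16) and WT 3 (-2.73), the 2 males with the highest *Saa1*. Whether it stands for clock phase in either sex was not tested. Feeding before collection and litter may also contribute and were not tested, and a link to *Ubiad1* remains a hypothesis because its transcript was not lower in Het.

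Other assignments of the genotype labels were drawn 100 times per comparison. As many genes as the 297 in males came from 2 of 100 draws, the real one included, a share under 0.05. The other draw, with 10 of 16 mice grouped as in the real labels, called 554 genes. Its rank correlation of log2 fold change with length was -0.48, against -0.49 for the real labels. A chance division of male libraries with unlike trends is therefore not excluded, and the 554 calls point to a structure of these libraries. As many as the 35 in females came from 1 of 100 draws (highest other 2), and as many as the 548 sex differences from 1 of 100 (highest other 335). As many lists as the 8 in males came from 26 of 100 draws (highest other 17), and as many as the 9 in females from 20 of 100 (highest other 12), so chance cannot be excluded for the number of lists.

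For 16 of 192 groups of 8 values, the highest or lowest mouse stood apart from the others by a gap, as a share of the whole range, above Dixon's 95% critical value, where chance gives about 1 in 20. In females this gap was 0.577 for *Acly* (Het 3), 0.640 for *Eif3f* (WT 1), 0.578 for *Eif3f* (Het 2), 0.542 for *Hipk2* (WT 1, lowest), 0.643 for *Hmox1* (Het 6), 0.704 for *Lss* (Het 3), 0.545 for *Per1* (WT 3), 0.634 for *Sox9* (WT 4) and 0.52602 for *Zfp472* (WT 6). In males it was 0.543 for *Bloc1s1* (WT 8), 0.599 for *Lum* (Het 4), 0.529 for *Mir6236* (WT 5, lowest), 0.591 for *Mir6236* (Het 7), 0.537 for *Saa1* (Het 2), 0.52624 for *Saa3* (Het 2) and 0.545 for *Scand1* (Het 4).

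The effect of the label differed between the sexes, by the interaction test in edgeR, for 548 genes. Among the named genes, the male minus female difference in log2 fold change was negative for *Bcl6* (-3.06), *Armcx4* (-1.72), *Plk3* (-1.52), *Tsc22d3* (-1.24), *Hipk2* (-1.22), *Btg2* (-1.21), *Adamts9* (-1.07), *Gfod1* (-1.06), *F8* (-1.05), *Pck1* (-1.03), *Arhgap31* (-1.02), *Ptch1* (-0.93), *Adgrl4* (-0.90), *Akap13* (-0.89) and *Stab2* (-0.62). It was positive for *Ndufaf8* (1.29), *Smim36* (1.05), *Fahd1* (1.03), *Eif3f* (0.98) and *Ndufs3* (0.86). With length and GC trends removed, 118 genes differed, and 10 of these 20 no longer passed: *Pck1* (adjusted p = 0.0638), *Ndufaf8* (0.0569), *Smim36* (0.0808), *Btg2* (0.0746), *Plk3* (0.123), *Adamts9* (0.126), *Arhgap31* (0.136), *Ptch1* (0.153), *Gfod1* (0.238) and *Stab2* (0.415). All 20 kept their sign. Of these 10, the difference stayed about as large for *Btg2* (-1.23), *Plk3* (-1.41), *Pck1* (-1.02) and *Smim36* (0.99). It shrank more for *Ndufaf8* (1.045), *Adamts9* (-0.73), *Gfod1* (-0.71), *Arhgap31* (-0.64), *Ptch1* (-0.57) and *Stab2* (-0.26). With the statistics rescaled to their robust spread, 0 passed in the edgeR fit (466 at an unadjusted p under 0.05). Sex and library batch cannot be told apart in these tables, since each table holds 1 sex.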

How the results depend on the processing

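The fits with length and GC trends removed, without the libraries that rose most with length or fell most with GC, with the clock score and with the authors' deposited adjusted p, as well as the permutation of list means and lists with mice left out, were chosen after seeing the data; unless given below, the cause of a change was not tested. In males, against 297 called genes, there were 1008 at adjusted p under 0.1, 19 under 0.01, 71 with a fold of at least 1.5, 4 with Benjamini-Yekutieli, 901 with DESeq2 (288 of the 297 among them), 7 with trends removed, 83 with the clock score and 0 without WT 1 to WT 5 (edgeR, 901 at an unadjusted p under 0.05; fewer mice). In females, against 35, there were 90 at adjusted p under 0.1, 1 under 0.01, 1 with Benjamini-Yekutieli, 239 with DESeq2 (all 35 among them), 76 in 1 fit over all groups, 97 in the authors' deposited table, 88 with trends removed, 57 with the clock score and 2 without the 4 libraries that fell most with GC. With 1 mouse left out, males gave 70 (WT 2) to 1342 (WT 8), with 123 (WT 1), 124 (WT 3), 94 (WT 4), 77 (WT 5), 1020 (WT 7), 109, 110, 148, 73, 171, 146 and 138 (Het 1, 3, 4, 5, 6, 7 and 8); WT 6 and Het 2 moved it by no more than 1.5 times. Females gave 3 (WT 8) to 69 (Het 6), with 16 (WT 1), 18 (WT 2), 20 (WT 4), 11 (WT 6), 13 (WT 7), 22, 13, 12, 20, 10 and 17 (Het 1, 3, 4, 5, 7 and 8); WT 3, WT 5 and Het 2 moved it by no more than that. Of the named called genes, 9 of 23 in males and 2 of 20 in females stayed called in each such fit, with 0 changes of sign. Called lists in males (8) were 0 with an estimated correlation (1 at an unadjusted p under 0.05), 0 by permutation of list means (6), 4 without WT 1 to WT 5 (1 of the 8 among them) and 5 with the clock score (4 of the 8); in females (9) they were 0 with an estimated correlation (4 at an unadjusted p under 0.05), 3 by permutation, 8 without the 4 GC libraries (5 of the 9) and 13 with the clock score (8 of the 9). With mice left out they were 7 to 9 in males and 6 to 12 in females. By fry, run without trend removal, coenzyme Q (adjusted p = 0.0207) and sterol regulation (0.0446) passed in males and cholesterol synthesis did not (0.0978). In females fatty acid and triglyceride synthesis (0.0109), glucose metabolism (0.0109), cholesterol synthesis (0.0234) and sterol regulation (0.0352) passed by fry. No other list passed by fry in either sex. Without WT 1 to WT 5 the sign turned for *Hipk2* (0.046), *Saa3* (0.048) and *Cdh5* (0.061) in males and for fatty acid oxidation (adjusted p = 0.877); with DESeq2 it turned for *Saa2* (0.17), with the clock score for acute phase genes in males (adjusted p = 0.769) and with trends removed for mitochondrially encoded genes in females (adjusted p = 0.814). Sex differences, against 548, were 1095 at adjusted p under 0.1, 188 among genes called in a sex, 118 with trends removed and 0 rescaled to the robust spread (edgeR, 466 at an unadjusted p under 0.05). Genes past the threshold in both sexes, against 0, were 434 at an unadjusted p under 0.05, of which 339 moved in opposite directions. At an adjusted p under 0.1 they were 10, of which 8 were opposite (3.67 expected) and 2 higher in both (2.63 expected). The correlation between the sexes, 0.02, was 0.044 at a mean count of at least 100, 0.067 among called genes, 0.094 with trends removed and -0.16 for test statistics. The counts stayed within 1.5 times with a mean count of at least 100 (361 in males, 31 in females, 589 sex differences), in 1 fit over all groups and in the authors' deposited table in males (329 and 351) and with a fold of at least 1.5 in females (25). Of the named genes, 34 of 50 in males and 28 of 44 in females kept their side of the threshold with DESeq2. In 1 fit over all groups 36 of 46 and 35 of 43 did, with trends removed 31 and 35, and with the clock score 38 and 39. Without those 5 or 4 libraries 24 and 26 did. These counts include named genes that were not called, which keep their side by staying uncalled. Of the 23 named called genes in males and 20 in females, 19 and 5 lost the call with trends removed. It was lost by 12 and 3 with the clock score, and by 23 and 18 without those libraries. Of the called lists, 6 of 8 in males and 6 of 9 in females stayed called with a correlation preset at 0.05, and 8 and 8 with ranks. No paired analysis was possible because each replicate number names a separate mouse and links no mice across groups. The rescaling of deposited p-values and the pseudocount setting were not run, since the tables held counts.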

Other observations

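The list of glucocorticoid targets was drawn up and tested only after the results were seen. In Het females, *Tsc22d3* rose by 1.43 ± 0.21 on the log2 scale, and *Tat*, a glucocorticoid-induced enzyme of tyrosine breakdown named after its value was seen, rose by 1.13 (edgeR adjusted p = 0.0120 for each). *Per1*, a clock gene that glucocorticoids also induce, had 1.92 ± 0.40 and did not pass (adjusted p = 0.0519). A hypothesis is that glucocorticoid receptor targets as a group were higher in these females. Of 15 other targets 13 were measured, 10 of them positive, with a median log2 fold change of 0.52 (camera with an estimated correlation, p = 0.0231). Their mean per mouse was 0.54 ± 0.17 higher in Het (exact permutation test, p = 0.00373), while 0 of the 13 were called, and *Fkbp5* (-0.01) and *Klf9* (-0.10), which are also known targets, were near 0. In males 5 of 13 were positive (median -0.09, p = 0.814 with an estimated correlation). The values are consistent with a difference in glucocorticoid exposure between the females of the 2 labels, whose source, such as handling or the time of collection, was not tested.

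The integrated stress response list was not called in females (median 0.00, camera adjusted p = 0.892), but its members went apart. *Herpud1* (0.80) and *Chac1* (1.21) rose and *Xbp1* (-0.38) fell when adjusted over the list alone, and none of the 3 was called over all genes. The circadian clock list was not called in males (median 0.26, adjusted p = 0.806) or females (median 0.05, adjusted p = 0.264). Within it *Clock* in males (-0.57, adjusted p = 0.0516) fell and *Per1* in females rose when adjusted over the list alone. Male-biased liver genes were negative in 10 of 13 cases in Het males (median -0.21, adjusted p = 0.144), and female-biased ones in 11 of 14 cases in Het females (median -0.39, adjusted p = 0.1596).

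The 2 males with the highest *Saa1* (WT 1 and WT 3) also had the lowest clock scores of the males, -4.16 and -2.73, against -1.70 to 2.29 in the other 14. *Lcn2*, another acute phase gene, stood at 705 CPM in WT 1 and 1093 CPM in WT 3. No comparison of these mice with others was made, since they were picked by their values.

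With length and GC trends removed, 81 genes were higher in Het of both sexes at an unadjusted p under 0.05, against 54.2 expected (exact one-sided test, p = 0.000143, genes not independent), while 67 were lower in both, against 76.0 expected, and 162 moved in opposite directions, against 130 expected. Without that step 67 were higher in both, against 85.6 expected, and 339 moved in opposite directions, against 199 expected.

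The share of counts in mitochondrial genes was 11.996% to 18.1% in males and 5.77% to 9.98% in females. *Nnt*, which carries a deletion in a related substrain, was listed in the female table alone and had a log2 fold change of 0.07 there. Why it was missing in males was not tested, so this gene leaves the strain given for the males unchecked. Markers of the pancreas were measured in 0 cases and of adipocytes in 1 case per sex.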
